A study of Homo sapiens with 16 samples.

How the data were processed

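The deposited files held 2 columns, gene symbol and counts, with 1 file for each of the 16 libraries, and the values were whole numbers that were used as counts without rescaling. The 8 RNA files each listed 56505 symbols and 5 summary lines of unassigned reads. The RPF files listed only genes with at least 1 count, nearly all of them protein-coding, and a gene missing from such a file was taken as 0. RNA and RPF reads had thus been counted over different features, so an absolute ratio of footprints to RNA was not interpretable and only its change between groups was tested. The submitters' processing notes name Bowtie, STAR and GRCh38 without versions or roles. The counting program, the annotation release and the strand setting were not given in the sources used here.

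Gene counts per library ran from 2294402 to 4707687 in RNA and from 2149347 to 3220657 in RPF. Reads that could be placed in genes made up 27.0 to 34.7% of the counted total in RNA and 15.0 to 32.1% in RPF, and reads placed at several sites made up 40.8 to 50.7% and 58.8 to 71.4%. Mitochondrial ribosomal RNA took 21.7 to 27.6% of RNA gene counts and mitochondrial tRNA 9.85 to 21.5%. The symbols ZNF773 and RP3-454G6.2 together took 1.98 to 17.0% of RNA gene counts. Near-identical copies such as HSPA1A and HSPA1B, the histone genes and CTAG2 may have lost reads or shared them.

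Gene locations came from GENCODE release 29 on GRCh38. Of the 56505 symbols, 37242 matched directly, 29 matched through an older or newer symbol, 115 were ambiguous and 19119 had no match. Unmatched genes stayed in the main tests. They were left out of the window analysis, the test of flanking genes and the RNA tests on protein-coding genes only. The tests of coding length and of short nuclear genes left them out too. In the fits with the change of neighbouring genes removed they stayed in without correction.

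The comparisons, alternatives, gene lists and the rule for naming genes were chosen from the labels before the data were examined. Genes with at least 10 counts in at least 2 libraries were tested, which left 12705 in RNA, 11171 in RPF and 10674 in both. Normalisation used TMM, and edgeR 4.0.16 quasi-likelihood models with genotype and time terms were fitted to the 8 libraries of each assay, leaving 3 residual degrees of freedom. Each KO was compared with WT, 12 h with 4 h, and the double KO with the sum of both single KOs on the log2 scale. The sum test asks for a departure from additivity. Whether the time change differed with loss of ATXN2 or of ATXN2L was tested with 1 residual degree of freedom. Translation efficiency (TE) was the difference between assays of a fold change, fitted on all 16 libraries with 6 residual degrees of freedom. P values were adjusted over all genes of a comparison by Benjamini and Hochberg at 0.05, and counts of changed genes refer to that level. Standard errors were the fold change divided by the square root of the edgeR F statistic. The biological coefficient of variation was 11.9% in RNA, 9.34% in RPF and 9.00% in the joint fit.

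The 25 gene lists with 591 members were written from general knowledge and tested with camera in limma 3.58.1 on log2 CPM (counts scaled to a common library total, prior count 3) with an inter-gene correlation of 0.01. They covered the core clock, glucocorticoid-induced genes, stress granule proteins, processing body (P-body) proteins, ribosomal proteins, other terminal oligopyrimidine (TOP) mRNAs, initiation factors and nuclear oxidative phosphorylation genes. They also covered mitochondrially encoded mRNAs, S phase, G2/M, the integrated stress response driven by ATF4, the endoplasmic reticulum (ER) unfolded protein response, heat shock, p53 targets and cholesterol synthesis. Glycolysis and hypoxia, NF-kB and inflammation, interferon response, immediate early genes, and osteoblast matrix genes followed. Marker lists for epithelial, endothelial, neuronal and blood cells completed the set, and no member of the blood list could be tested. P values were adjusted over the lists within a comparison. The alternatives were camera with an estimated correlation and fry.

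ATXN2 and ATXN2L were named first, with every library. Further genes were the strongest by log2 fold change among those passing, with average log2 CPM of at least 3 and the same sign at both times, or in all 4 lines for the time change. RPF contributed up to 5 each way, and RNA and TE contributed up to 4 each way. No rule on sign was applied to genes named for the departure, time change by loss, or the double KO against a single KO. Clone-named genes and pseudogenes were passed over, and where nothing passed the smallest p were named. Passing lists contributed their members with the smallest p. In groups with 0 counts a ratio bound was set at 3 counts, and with 1 to 3 counts an exact ratio interval at 95% was given. Those bounds and intervals cover counting error only.

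The alternatives were RLE normalisation, DESeq2 1.42.0, no filter, leaving out each library in turn (in TE the pair of RNA and RPF libraries), a fit of only the 2 genotypes compared, no time term, and limma on per-pair TE differences. Alternatives added after the results were seen were RNA tests on protein-coding genes only, TE tests without mitochondrial genes, and fits with the change of neighbouring genes removed. The comparisons of the double KO with each single KO and the list tests without the 4 h ATXN2L KO libraries were also added then. A search for shifted chromosome windows was added as well. It used the median change of 40 neighbouring protein-coding genes in both assays against 100 permutations of gene order, giving 263 windows.

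Changes were planted in simulated counts to test the methods. The RNA test of the ATXN2 KO recovered 75% of 2-fold and 99% of 4-fold changes, and the RPF test recovered 79% and 100%. Recovery in TE was 47% and 93%, and the departure test recovered 36% and 92% in RNA. A planted list was found with 0 other lists called, among random lists whose genes varied independently of one another. That test could not show false list calls from correlation between genes. In the test of the later window search 6 planted windows were found with 0 false ones. R was version 4.3.3.

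Read alignment, reading frame, pauses and start sites were not examined, because only gene counts were used. Circadian period and phase were not estimated from 2 times.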

Results

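The series profiled RNA and translation in U2OS, an established human osteosarcoma (bone cancer) cell line often used to study the circadian clock. Its 4 genotypes were the unedited line (WT), a knockout (KO) of ATXN2, a KO of ATXN2L, and a double KO. ATXN2 and its paralog ATXN2L encode RNA-binding proteins that bind poly(A)-binding protein and enter stress granules. Cells were collected 4 h and 12 h after 200 nM DXMS, taken here to be dexamethasone, a synthetic glucocorticoid that brings cultured cells to a common clock phase. Each genotype, time and assay had 1 library, either of fragmented total RNA or of ribosome-protected fragments (RPF). RPF libraries, made here with an ARTseq kit, hold the short mRNA pieces that translating ribosomes shield from nuclease. The p values of the KO comparisons therefore measure the spread of a genotype difference between the 2 times, in 1 line per genotype with no independent clones stated. Fold changes are log2 values ± standard error with edgeR adjusted p unless another tool is named. The most strongly changed genes named for a KO against WT had their direction at both times, and those for the time change had it in all 4 lines. No such rule held for list members, the departure from the sum, time change by loss, or the double KO against a single KO.

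The targeted genes lost reads in the lines labelled as their KOs, although reads remained in each. ATXN2 (GRCh38 chromosome 12, 111443485 to 111599676) had RPF levels of 43.5 and 74.4 CPM in WT at 4 h and 12 h. They were 14.9 and 10.5 CPM in the ATXN2 KO, 92.9 and 107 CPM in the ATXN2L KO and 13.8 and 19.6 CPM in the double KO. ATXN2L (chromosome 16, 28823035 to 28837237) had 158 and 166 CPM in WT, 149 and 140 CPM in the ATXN2 KO, 65.0 and 60.3 CPM in the ATXN2L KO, and 24.6 and 22.8 CPM in the double KO. ATXN2 footprints were thus 4.56-fold lower in the ATXN2 KO (-2.19 ± 0.24, edgeR adjusted p = 5.32e-06) and also lower in the double KO (-1.81 ± 0.23, adjusted p = 1.63e-05). ATXN2L footprints were lower in the ATXN2L KO (-1.37 ± 0.14, edgeR adjusted p = 1.54e-06) and 6.84-fold lower in the double KO (-2.77 ± 0.15, adjusted p = 3.76e-10). ATXN2L footprints did not pass in the ATXN2 KO (-0.17 ± 0.13, edgeR adjusted p = 0.406). ATXN2 footprints rose in the ATXN2L KO (0.77 ± 0.19, edgeR adjusted p = 0.00683), a call lost without the WT 4 h library or without the ATXN2L KO 4 h library (edgeR adjusted p up to 0.213).

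RNA of the targeted genes changed less than footprints for ATXN2. ATXN2 RNA stood at 23.4 and 24.8 CPM in WT, 11.1 and 15.3 CPM in its KO, 30.6 and 35.3 CPM in the ATXN2L KO and 11.9 and 16.9 CPM in the double KO. ATXN2L RNA stood at 83.4 and 79.4 CPM in WT, 69.9 and 70.1 CPM in the ATXN2 KO, 32.2 and 30.6 CPM in its KO and 15.5 and 26.3 CPM in the double KO. ATXN2L RNA fell by 1.36 ± 0.17 in its KO (edgeR adjusted p = 5.58e-06) and by 2.01 ± 0.20 in the double KO (adjusted p = 2.74e-07). ATXN2 RNA fell by 0.86 ± 0.22 in its KO (edgeR adjusted p = 0.0099) and by 0.76 ± 0.23 in the double KO (adjusted p = 0.0312). The ATXN2 RNA call in its KO was lost without the WT 4 h, ATXN2 KO 4 h or ATXN2 KO 12 h library (edgeR adjusted p up to 0.134). In the double KO it was lost without the WT 4 h, WT 12 h, double KO 4 h or double KO 12 h library (edgeR adjusted p up to 0.281). The edited parts of the genes were not stated, so counts over whole genes do not test loss of protein.

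**Figure D1:**
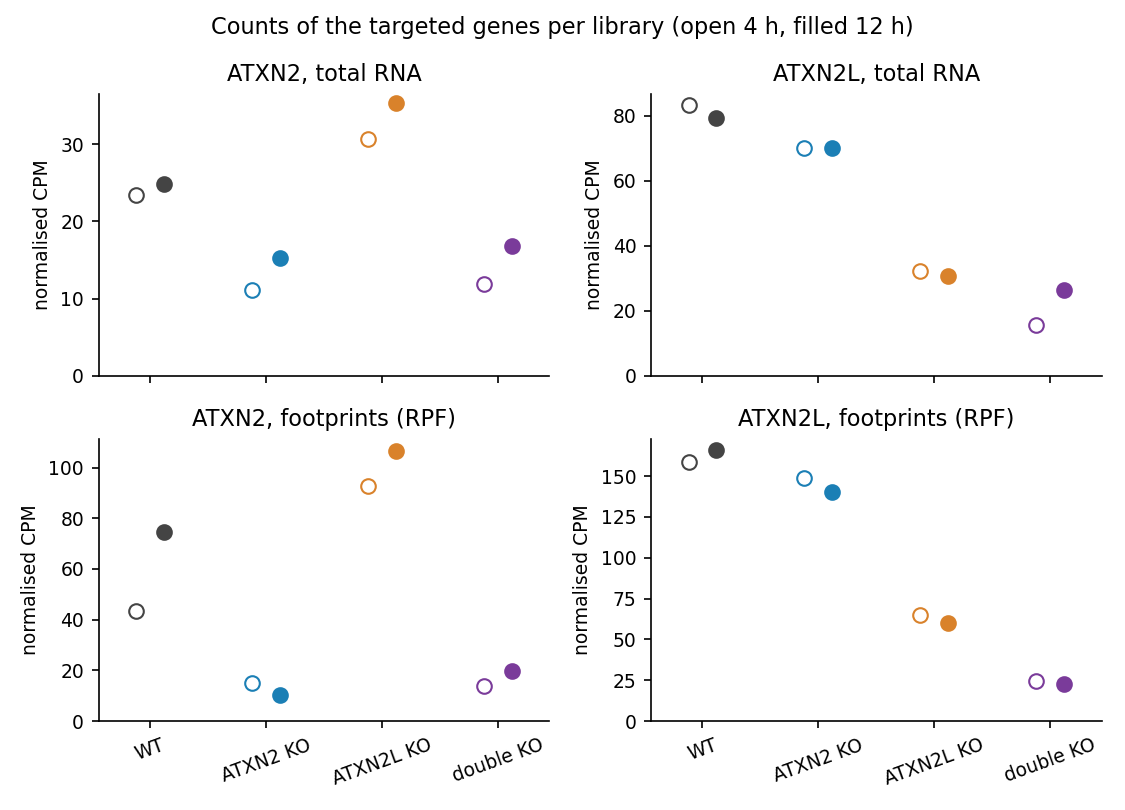
Normalised CPM of ATXN2 and ATXN2L in each library of the 4 genotypes, with RNA above, RPF below, open symbols for 4 h and filled symbols for 12 h. ATXN2 footprints were 14.9 and 10.5 CPM in the ATXN2 KO, and ATXN2L footprints were 24.6 and 22.8 CPM in the double KO.

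ATXN2 encodes an RNA-binding protein linked to mRNA stability and, in flies, to translation of the clock gene period. IGFBP3 and IGFBP4, which encode proteins that bind insulin-like growth factors, fell strongly, as did HIST1H4C and NES. The transcription factor p53 drives genes of cell cycle arrest and DNA repair such as CDKN1A. ER chaperones such as HSP90B1 fold secreted and membrane proteins.

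In RPF 2167 genes changed in the ATXN2 KO, 1021 higher and 1146 lower, and 708 of them changed at least 2-fold. The count fell to 613 without the WT 4 h library, 1109 without WT 12 h, 1164 without the ATXN2 KO 4 h library and 1032 without its 12 h library. The amino acid transporter gene SLC7A10 had 155 footprint counts against 1 in WT (ratio 138, exact interval 24.4 to 5483). The inflammasome gene NLRP2 (4.63 ± 0.36), the small heat shock protein gene HSPB7 (4.37 ± 0.43) and the matrix proteoglycan gene BGN (4.02 ± 0.35) rose. The transcription factor gene GATA6 had 64 counts against 3 (ratio 19.0, exact interval 6.21 to 94.5). RGS10, a regulator of G protein signalling, had 0 counts against 99 in WT, at least 37.1-fold lower, and lay in a stretch of chromosome 10 where most genes were lower. IGFBP4, which binds insulin-like growth factors, had 2 counts against 296 (ratio 166, exact interval 45.6 to 1379.6). Histone gene HIST1H4C (-6.01 ± 0.25), SERPINF1, encoding a secreted neurotrophic factor (-4.59 ± 0.34), and NES, encoding nestin (-4.53 ± 0.34), fell.

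In RNA 1623 genes changed in the ATXN2 KO, 688 higher and 935 lower. The count was 789 without WT 4 h, 904 without WT 12 h, 591 without the ATXN2 KO 4 h library and 478 without its 12 h library. The microRNA cluster members MIR96 (5.33 ± 0.46) and MIR182 (4.47 ± 0.48) rose, and MIR183 of the same cluster had 90 counts against 2 (ratio 40.9, exact interval 10.99 to 343). SCX, a tendon transcription factor gene, had 123 counts against 3 (ratio 37.2, exact interval 12.4 to 183). IGFBP4 (-5.22 ± 0.33), HIST1H4C (-4.11 ± 0.21) and NES (-3.48 ± 0.36) fell as in RPF. IGFBP3 fell by 6.16 ± 0.30 within a stretch of chromosome 7 that was lower as a whole.

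Among gene lists in the ATXN2 KO, p53 targets were lower in RPF, where 0 rose, 10 fell and 10 did not pass (12 fell when adjusted over the list alone). Their camera adjusted p was 1.37e-06, and adjusted p = 0.231 with an estimated correlation. The p53 target CDKN1A, a cell cycle inhibitor gene, fell by 1.33 ± 0.17 although its stretch of chromosome 6 was higher. FDXR (-1.67 ± 0.18) fell in a chromosome 17 stretch that was lower as a whole. In RNA 8 p53 targets fell and 11 did not pass (11 fell over the list alone), with camera adjusted p = 0.000231, and adjusted p = 0.778 with an estimated correlation. The ER unfolded protein response list was higher in RPF, with 7 rising, 0 falling and 11 not passing (9 over the list alone). Its camera adjusted p was 0.00162, and adjusted p = 0.914 with an estimated correlation. The ER chaperone gene HSP90B1 rose by 0.80 ± 0.14. In RNA 3 of its members rose and 15 did not pass (8 rose over the list alone), with camera adjusted p = 0.00348, and adjusted p = 0.786 with an estimated correlation.

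Cholesterol synthesis was higher in RPF of the ATXN2 KO, with 8 genes up, 1 down and 13 not passing (9 and 1 over the list alone). Camera gave adjusted p = 0.00581, and adjusted p = 0.855 with an estimated correlation, and DHCR7, encoding the last enzyme of the pathway, rose by 0.95 ± 0.12. In RNA 6 cholesterol genes rose and 16 did not pass (7 over the list alone), with camera adjusted p = 0.0231, and adjusted p = 0.786 with an estimated correlation. Ribosomal protein genes were slightly lower in RPF (median -0.25), with 0 up, 14 down and 52 not passing (15 down over the list alone). Camera gave adjusted p = 0.000365, and adjusted p = 0.914 with an estimated correlation. In RNA 1 ribosomal protein gene rose, 12 fell and 66 did not pass (1 and 18 over the list alone), with camera adjusted p = 0.00266, and adjusted p = 0.786 with an estimated correlation. Interferon response genes fell in RPF (0 up, 5 down, 5 not passing, and 5 down over the list alone), with camera adjusted p = 0.0315, and adjusted p = 0.555 with an estimated correlation. The interferon-induced gene IFI44 had 3 counts against 82 in WT (ratio 30.7, exact interval 10.1 to 152). Mitochondrially encoded mRNAs fell in RNA, with 4 down and 9 not passing (5 over the list alone), camera adjusted p = 0.0223, and adjusted p = 0.786 with an estimated correlation. The small neuronal marker list fell in RPF (2 of 3, or 3 over the list alone, camera adjusted p = 0.0177), and adjusted p = 0.555 with an estimated correlation. It also fell in RNA (2 of 4, also 2 over the list alone, camera adjusted p = 0.00418), and adjusted p = 0.778 with an estimated correlation. NEFL, encoding neurofilament light chain, fell by 2.86 ± 0.17 in RNA and by 0.99 ± 0.16 in RPF.

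The ATXN2L KO shared many of its strongest changes with the ATXN2 KO, among them SLC7A10, NLRP2 and IGFBP4. ATF4 is the transcription factor of the integrated stress response and drives serine and one-carbon synthesis. Glycolytic enzymes such as GAPDH and ALDOA turn glucose to pyruvate.

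In RPF 2540 genes changed in the ATXN2L KO, 1201 higher and 1339 lower, and the count was 976 without WT 4 h and 1097 without WT 12 h. CTAG2, a cancer and testis antigen gene with near-identical copies, had 215 footprint counts against 2 (ratio 98.1, exact interval 26.8 to 815). SLC7A10 had 108 counts against 1 (ratio 98.5, exact interval 17.3 to 3928), and NLRP2 rose by 4.85 ± 0.36. TRIM29 had 81 counts against 3 (ratio 24.6, exact interval 8.14 to 122) and GATA6 had 39 against 3 (ratio 11.9, exact interval 3.77 to 59.997). SERPINF1 had 2 counts against 262 (ratio 144, exact interval 39.4 to 1192). IGFBP4 (-5.46 ± 0.51), HIST1H4C (-5.18 ± 0.23), the synaptic vesicle gene SYT2 (-4.37 ± 0.46) and the T-cell adaptor gene LAT (-4.13 ± 0.41) fell.

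In RNA 2445 genes changed in the ATXN2L KO, 1080 higher and 1365 lower. The count was 1219 without WT 4 h, 1279 without WT 12 h and 1368 without the ATXN2L KO 4 h library. MIR96 (5.08 ± 0.47) and MIR182 (4.31 ± 0.48) rose, MIR183 had 56 counts against 2 (ratio 20.7, exact interval 5.46 to 175) and SCX had 84 against 3 (ratio 20.7, exact interval 6.83 to 102.2). IGFBP4 had 3 counts against 355 (ratio 160.4, exact interval 54.4 to 781). IGFBP3 (-5.76 ± 0.28), HIST1H4C (-4.51 ± 0.21) and the mitochondrial methionine tRNA gene MT-TM (-3.67 ± 0.23) fell. MT-TM reads depend on how a library recovers short RNA.

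Ribosomal protein RNA was lower in the ATXN2L KO (median -0.42), with 0 up, 34 down and 45 not passing of 79 (45 down over the list alone). Camera gave adjusted p = 3.86e-10, and adjusted p = 0.564 with an estimated correlation, and RPS29 (-1.15 ± 0.15) and RPLP1 (-1.02) had small p. In RPF 2 ribosomal protein genes rose, 17 fell and 47 did not pass (2 and 21 over the list alone), with camera adjusted p = 0.000555, and adjusted p = 0.822 with an estimated correlation. Without the 4 h ATXN2L KO libraries the RPF list no longer passed (camera adjusted p = 0.548). Glycolysis and hypoxia genes were lower in RPF, with 0 up, 9 down and 11 not passing (1 and 9 over the list alone). Camera gave adjusted p = 0.000555, and adjusted p = 0.508 with an estimated correlation. PFKP, encoding a phosphofructokinase, fell by 1.08 ± 0.13, ALDOA fell by 0.90, and the hypoxia marker CA9 had 1 count against 83 (ratio 91.0, exact interval 15.9 to 3636). In RNA 6 glycolysis genes fell and 14 did not pass (10 fell over the list alone), with camera adjusted p = 0.00558, and adjusted p = 0.564 with an estimated correlation, and GAPDH fell by 0.83 ± 0.15.

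ATF4 targets were lower in RPF of the ATXN2L KO, with 0 up, 11 down and 14 not passing (12 over the list alone). Camera gave adjusted p = 0.0079, and adjusted p = 0.822 with an estimated correlation. The one-carbon enzyme gene MTHFD2 (-0.93 ± 0.15) and PHGDH of serine synthesis (-0.79) fell. In RNA 7 ATF4 targets fell and 18 did not pass (8 over the list alone), with camera adjusted p = 0.0362, and adjusted p = 0.564 with an estimated correlation, and ATF4 fell by 0.86 ± 0.15. Nuclear oxidative phosphorylation genes fell in RPF (3 up, 16 down, 53 not passing, and 3 and 16 over the list alone), with camera adjusted p = 0.0079, and adjusted p = 0.822 with an estimated correlation. UQCRC2 of respiratory complex III fell by 1.03 ± 0.13, but without the 4 h ATXN2L KO libraries the list did not pass (camera adjusted p = 0.274). Mitochondrially encoded RNA fell, with 8 down and 5 not passing (10 over the list alone), camera adjusted p = 3.47e-05, and adjusted p = 0.564 with an estimated correlation. G2/M genes rose in RNA (7 up, 0 down, 23 not passing, and 8 and 1 over the list alone), with camera adjusted p = 0.0478, and adjusted p = 0.564 with an estimated correlation, and TPX2, a spindle assembly gene, rose by 0.85 ± 0.14. Heat shock genes rose in RNA (4 up, 10 not passing, and 4 over the list alone), with camera adjusted p = 0.0371, and adjusted p = 0.748 with an estimated correlation, and the chaperone gene CRYAB rose by 1.74 ± 0.16, while DNAJB1 no longer rose once the change of its neighbours on chromosome 19 was removed (-0.014). Neuronal markers fell in RNA (2 of 4, also 2 over the list alone, camera adjusted p = 0.0362), and adjusted p = 0.564 with an estimated correlation, and NEFL fell by 2.73.

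The double KO combined both losses and most resembled the ATXN2 KO. Each ATXN2 KO footprint library correlated best with the double KO library of its time (0.981 at 4 h, 0.983 at 12 h). A common origin of both lines could bring this as well as the genotype, and the design cannot tell these apart. The same transporter, matrix and microRNA genes were higher, and the same IGF binding, histone and nestin genes were lower. BGN encodes biglycan, a small matrix proteoglycan of bone, and ADD2 encodes a protein of the spectrin skeleton.

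In RPF 2346 genes changed in the double KO, 1041 higher and 1305 lower. The count was 822 without WT 4 h, 1141 without WT 12 h, 1111 without the double KO 4 h library and 1221 without its 12 h library. SLC7A10 had 212 footprint counts against 1 (ratio 168, exact interval 29.8 to 6669). NLRP2 (4.77 ± 0.35), BGN (4.65 ± 0.33), HSPB7 (4.62 ± 0.42) and ADD2 (4.37 ± 0.54) rose. IGFBP4 had 2 counts against 296 (ratio 187, exact interval 51.2 to 1549), and RGS10, in its lower stretch of chromosome 10, had 3 against 99 (ratio 41.6, exact interval 13.8 to 205). HIST1H4C (-6.58 ± 0.26), SERPINF1 (-6.27 ± 0.41) and NES (-4.99 ± 0.35) fell. In RNA 1640 genes changed, 695 higher and 945 lower, with 849 without WT 4 h, 969 without WT 12 h, 787 without the double KO 4 h library and 1014 without its 12 h library. MIR96 (5.50 ± 0.46) and MIR182 (4.83 ± 0.47) rose in RNA, MIR183 had 58 counts against 2 (ratio 37.7, exact interval 9.99 to 319), and SCX had 84 against 3 (ratio 36.4, exact interval 12.1 to 180.3). IGFBP3 (-6.11 ± 0.33), HIST1H4C (-4.77 ± 0.25), IGFBP4 (-4.68 ± 0.34) and NES (-4.40 ± 0.45) fell in RNA.

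Glycolysis genes were lower in RPF of the double KO, with 1 up, 10 down and 9 not passing (1 and 10 over the list alone). Camera gave adjusted p = 0.00293, and adjusted p = 0.336 with an estimated correlation, and GAPDH fell by 1.05 ± 0.13 and PFKP by 0.79. In RNA 8 glycolysis genes fell and 12 did not pass (1 up and 8 down over the list alone), with camera adjusted p = 0.00923, and adjusted p = 0.757 with an estimated correlation. For p53 targets in RPF 0 rose, 9 fell and 11 did not pass (9 over the list alone), with camera adjusted p = 0.00293, and adjusted p = 0.336 with an estimated correlation, and RRM2B, a ribonucleotide reductase gene, fell by 0.90. In RNA 8 p53 targets fell and 11 did not pass (8 over the list alone), with camera adjusted p = 0.0257, and adjusted p = 0.757 with an estimated correlation. ER folding genes rose in RPF (5 up, 13 not passing, and 5 over the list alone), with camera adjusted p = 0.0333, and adjusted p = 0.922 with an estimated correlation. They also rose in RNA (3 up, 15 not passing, and 3 over the list alone), with camera adjusted p = 0.0268, and adjusted p = 0.757 with an estimated correlation. Interferon genes fell in RPF (3 down, 7 not passing, and 4 over the list alone), with camera adjusted p = 0.0438, and adjusted p = 0.434 with an estimated correlation, and IFI44 fell by 4.30. Neuronal markers fell in RPF (2 of 3, camera adjusted p = 0.0179), and adjusted p = 0.431 with an estimated correlation, where RBFOX3, a neuronal splicing factor gene, had 2 counts against 64 (ratio 40.4, exact interval 10.7 to 340). They fell in RNA too (2 of 4, camera adjusted p = 0.00923), and adjusted p = 0.757 with an estimated correlation, and NEFL fell by 2.90.

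**Figure D2:**
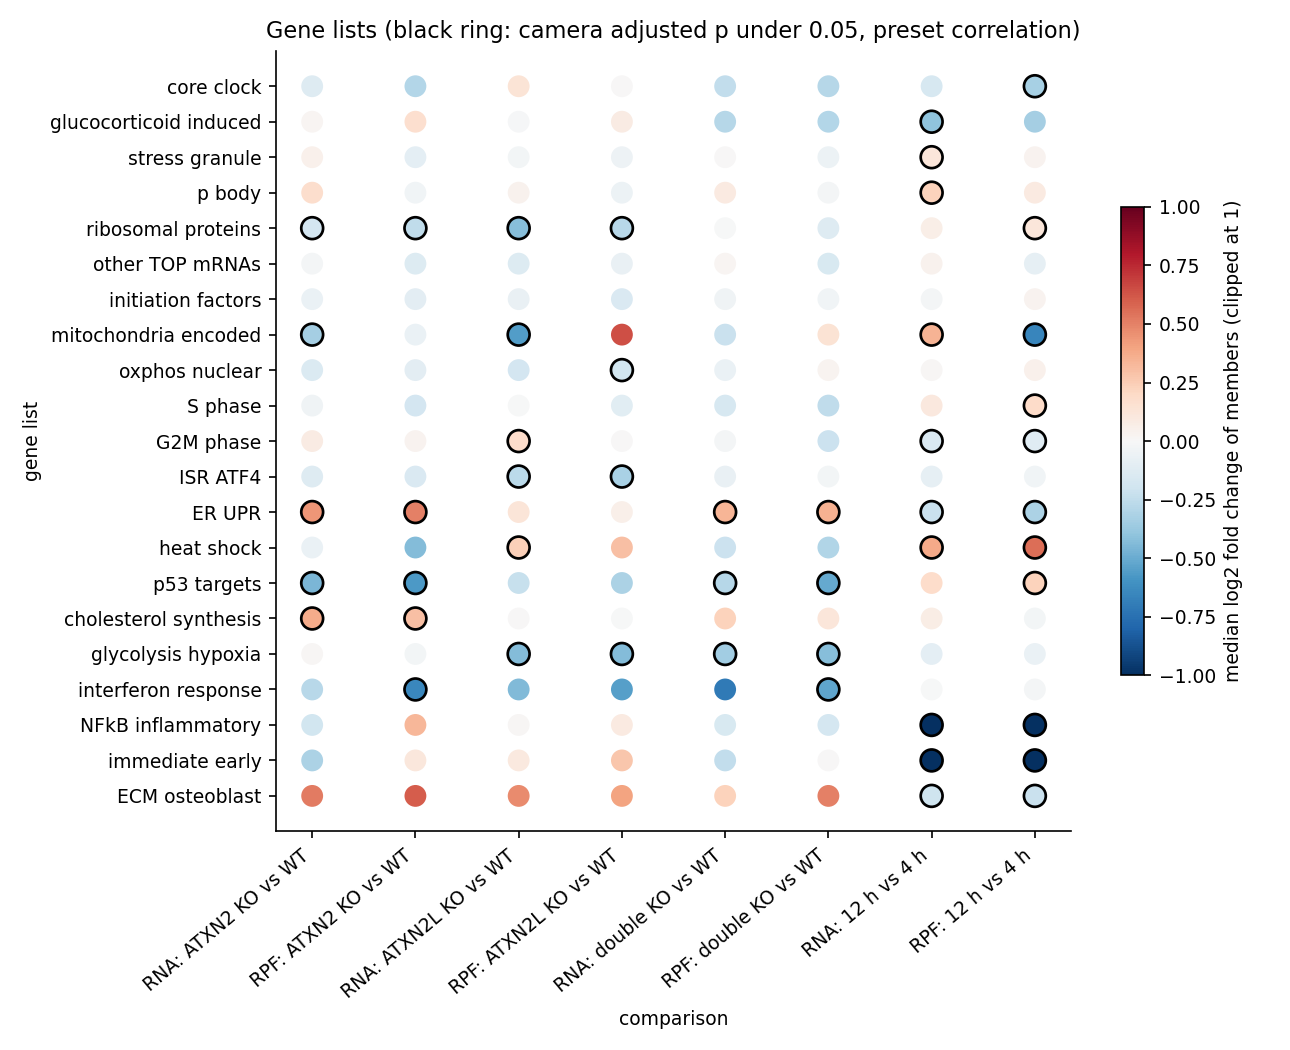
Median log2 fold change of each gene list in RNA and RPF for the 3 KO comparisons and the time comparison, with rings where camera adjusted p was under 0.05. NF-kB genes had medians of -1.83 in RNA and -1.93 in RPF over time, and glycolysis genes had -0.44 in ATXN2L KO RPF.

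The remaining lists did not pass in RPF for the ATXN2 KO, ATXN2L KO and double KO in that order. For p53 targets in the ATXN2L KO 0 rose, 7 fell and 13 did not pass (8 over the list alone), with camera adjusted p = 0.062. Core clock genes had camera adjusted p of 0.420, 0.770 and 0.347, stress granule genes 0.668, 0.542 and 0.280, and P-body genes 0.806, 0.710 and 0.815. Other TOP mRNAs, which like ribosomal protein mRNAs respond to growth signals, had camera adjusted p of 0.184, 0.770 and 0.144, and initiation factors 0.282, 0.140 and 0.603. Glucocorticoid-induced genes had camera adjusted p of 0.282, 0.284 and 0.815, S-phase genes 0.282, 0.620 and 0.0926, and heat shock genes 0.168, 0.174 and 0.195. NF-kB genes had camera adjusted p of 0.806, 0.798 and 0.661, immediate early genes 0.664, 0.0620 and 0.815, and osteoblast matrix genes 0.0837, 0.140 and 0.280. Matrix members moved both ways, with 10 up and 6 down in the ATXN2 KO. The epithelial and endothelial marker lists had 1 tested member each and passed nowhere, and the blood list had none.

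The 3 KO lines shared many changes against the same WT libraries. In RPF 957 genes changed with one sign in all 3 KOs, 422 higher and 535 lower, where independent lists of that size would share 26.3. With the change of neighbouring genes removed 554 genes did so, of which 460 were among the 957 (48.1%). In RNA 741 genes did so, 258 higher and 483 lower. The ATXN2 KO and double KO shared 1598 RPF changes with 0 in opposite directions, and their fold changes correlated at 0.882 across genes. The shared WT libraries alone bring a correlation, and simulated unchanged lines gave a median of 0.532 for this pair. The ATXN2 KO and ATXN2L KO shared 1151 with 27 in opposite directions (0.672 across genes, against 0.517 in simulated unchanged lines). The ATXN2L KO and double KO shared 1195 with 29 in opposite directions (0.694, against 0.530). IGFBP4, HIST1H4C and SERPINF1 were lower and SLC7A10 and NLRP2 higher in every KO.

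**Figure D3:**
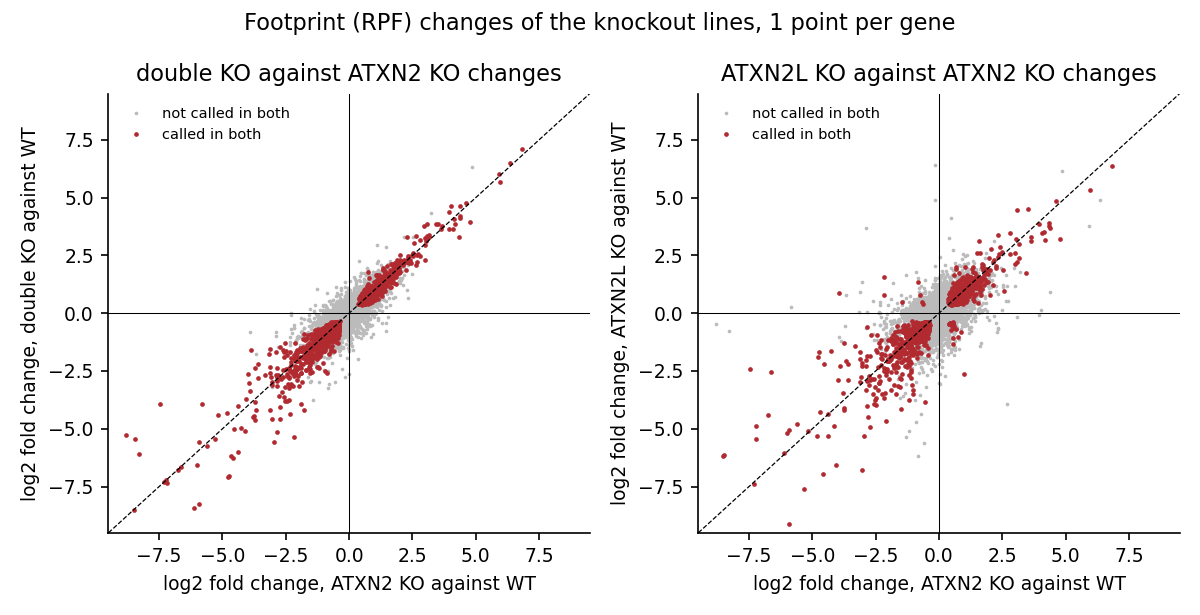
RPF log2 fold change in the ATXN2 KO (horizontal) against the double KO and the ATXN2L KO (vertical), one point per gene, with genes changed in both KOs in red. The correlation across genes was 0.882 with the double KO and 0.672 with the ATXN2L KO, where unchanged lines sharing WT gave 0.532 and 0.517 in simulation.

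Part of the KO changes followed chromosome position. Of 263 windows of 40 neighbouring genes, 18 were shifted in both assays in the ATXN2 KO (5 higher, 13 lower), 14 in the ATXN2L KO (14 higher) and 18 in the double KO (7 higher, 11 lower). The stretch of chromosome 10 from 119.5 to 133.4 Mb with RGS10 was lower in the ATXN2 KO and double KO (RPF medians -0.73 and -0.77). The stretch of chromosome 19 from 1.6 to 29.6 Mb, with DPP9, was higher in the ATXN2L KO in 7 windows, with RPF medians of 0.53 to 0.71. The ATXN2L KO also had a long run of windows on chromosome 1, from 19.3 to 121.4 Mb, that were all lower, with RNA medians of -0.18 to -0.57 and RPF medians of -0.24 to -0.47, and stayed short of the thresholds of 0.427 in RNA and 0.487 in RPF in at least 1 assay. The shifted windows held 6.56%, 5.22% and 6.77% of coding genes and 13.9%, 11.3% and 14.7% of those changed in RPF in the ATXN2 KO, ATXN2L KO and double KO, an excess that follows in part from choosing windows by these changes. With the change of neighbouring genes removed the RPF counts were 1415, 1469 and 1557 in the same order.

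**Figure D4:**
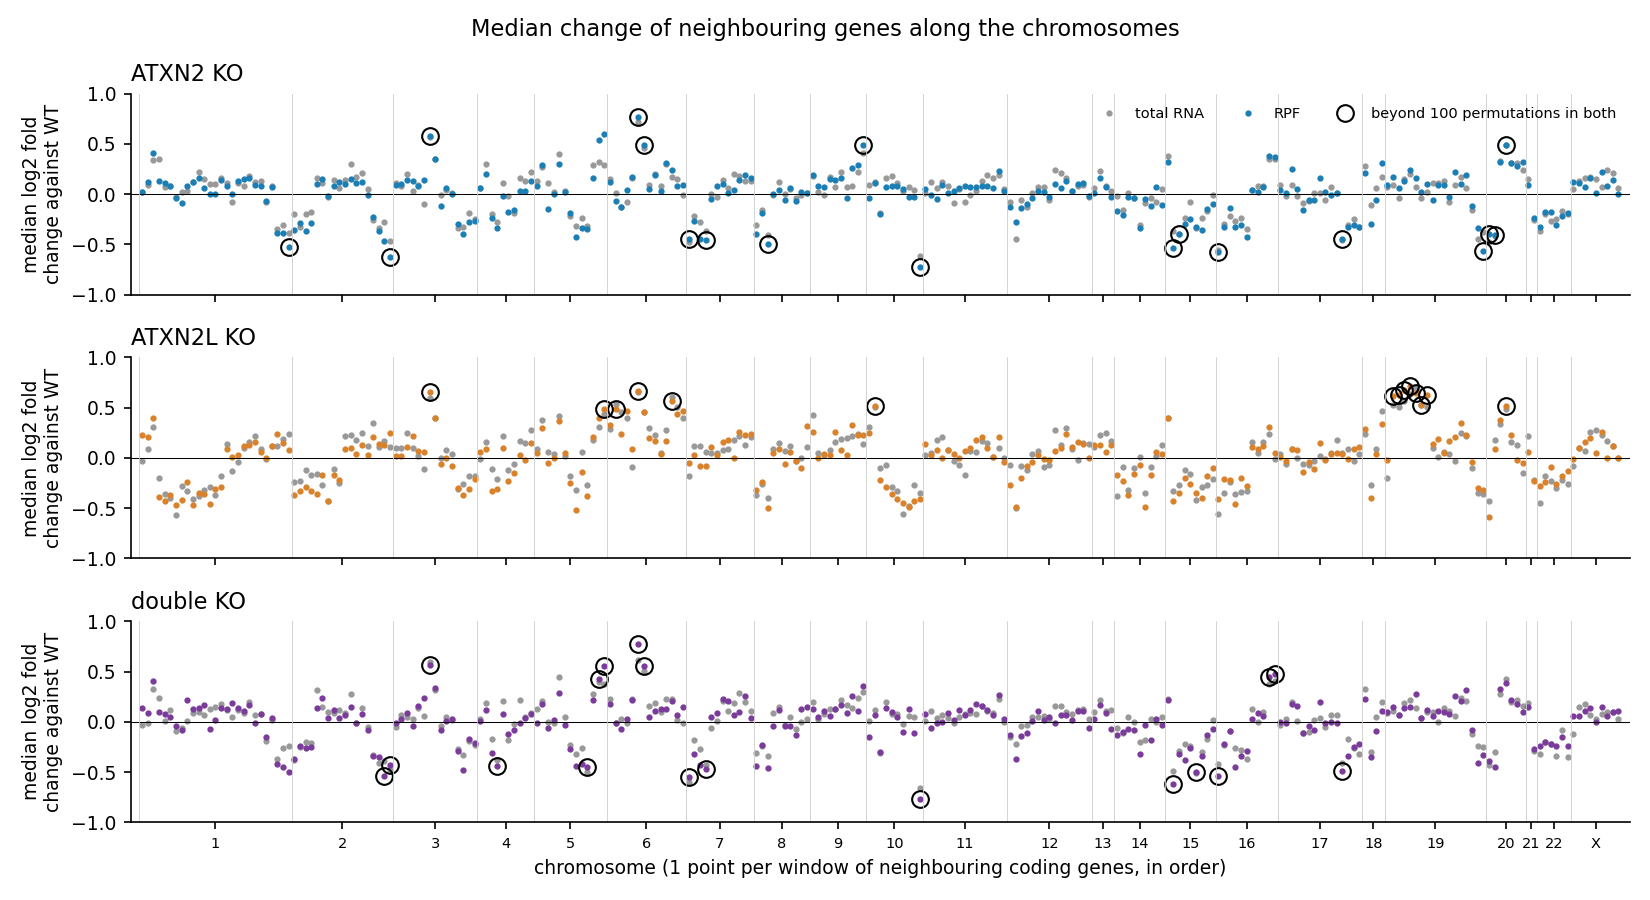
Median log2 fold change of windows of 40 coding genes along the chromosomes for each KO, RNA in grey and RPF in colour, with rings where both assays shifted beyond 100 permutations. Windows numbered 18, 14 and 18 for the ATXN2 KO, ATXN2L KO and double KO.

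If both proteins acted separately and the lines differed in nothing else, the double KO change would equal the sum of the single KO changes on the log2 scale. The departure test asks which genes moved away from that sum. Both single changes are taken against the same WT line, so a lasting feature of that line also gives a departure. The test cannot tell this from an interplay of both proteins. HIST1H4C, NLRP2, IGFBP3 and MIR96, named below, changed by similar amounts in every KO. SPP1 encodes osteopontin, a secreted bone protein, and NLRP2 an inflammasome protein. Departure was found for 1101 genes in RPF (534 above, 567 below the sum) and 868 in RNA (479 above, 389 below). HIST1H4C (4.61 ± 0.56) and SPP1 (4.29 ± 0.41) lay above the sum in RPF, while NLRP2 (-4.71 ± 0.43) lay below it. In RNA IGFBP3 (5.81 ± 0.98) and HIST1H4C (3.86 ± 0.52) lay above and MIR96 (-4.92 ± 0.56) below. SERPINF1, SLC7A10 and TRIM29 in RPF and IGFBP4, MIR183 and SCX in RNA had a group with 1 to 3 counts, so their sums lay beyond what counts can show and no size is given. ATXN2L footprints lay below the sum (-1.23 ± 0.21, edgeR adjusted p = 0.00129). The RPF count was 267 without WT 4 h, 453 without WT 12 h, 546 without ATXN2 KO 12 h, 494 without double KO 4 h and 576 without double KO 12 h. The RNA count was 553 without WT 4 h, 285 without ATXN2 KO 4 h, 227 without ATXN2 KO 12 h and 451 without double KO 4 h.

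The double KO was also compared directly with each single KO, a choice made after the first results. Against the ATXN2 KO 31 genes differed in RPF, 3 higher and 28 lower, and 8 in RNA. This was far fewer than the 2540 RPF genes changed in the ATXN2L KO against WT. With 1 line per genotype, an effect of losing ATXN2L cannot be told from other differences between the lines. ATXN2L (-2.61 ± 0.15), the procollagen enhancer gene PCOLCE (-2.42 ± 0.22) and the chemokine gene CCL20 (-1.85 ± 0.30) were lower in RPF, and IGFBP7 (1.23 ± 0.18) was higher. In RNA CFAP58 (1.48 ± 0.25) was higher, and ATXN2L (-1.80 ± 0.20) and the adhesion gene L1CAM (-1.79 ± 0.28) were lower. Calls lost in leave-one-out fits were CCL20 (without ATXN2 KO 4 h or double KO 4 h), IGFBP7 (without ATXN2 KO 12 h or double KO 4 h), CFAP58 RNA (without any ATXN2 KO or double KO library) and L1CAM (without ATXN2 KO 4 h, ATXN2 KO 12 h or double KO 4 h), with edgeR adjusted p up to 1, 0.139, 0.582 and 0.514. These RNA counts ran from 1 to 50 and the RPF counts from 3 to 121 when single libraries were left out. Against the ATXN2L KO 1597 genes differed in RPF (769 higher, 828 lower) and 932 in RNA (507 higher, 425 lower). BGN (4.51 ± 0.32), ADD2 (4.46 ± 0.54) and HSPB7 (3.69 ± 0.36) were higher and CTAG2 (-5.49 ± 0.46) and PCDHB8 (-3.90 ± 0.32) lower in RPF. Those counts were 545 without the double KO 4 h library and 702 without its 12 h library in RPF, and in RNA 329, 506 and 526 without double KO 4 h, double KO 12 h and ATXN2L KO 4 h.

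A glucocorticoid pulse induces PER1 and resets the clock in each cell. All libraries came from cells given DXMS, so without untreated cells a change from 4 h to 12 h cannot be tied to it. ARNTL (BMAL1) is the positive arm of the clock loop, and PER2, CRY2 and NR1D2 (REV-ERB beta) belong to its negative arms. NF-kB drives inflammatory genes such as the chemokines CXCL8 and CCL20. Between the collection times CXCL8, CCL20 and the NR4A genes declined, PER2 and NR1D2 fell, and ARNTL and HSPA1B rose.

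From 4 h to 12 h 1436 genes changed in RPF (559 up, 877 down) and 863 in RNA (374 up, 489 down). CXCL8 (-4.48 ± 0.45) and CCL20 (-4.35 ± 0.26) fell most in RPF, followed by the early nuclear receptor genes NR4A2 (-3.54 ± 0.36), NR4A3 (-3.27 ± 0.34) and NR4A1 (-3.01 ± 0.26). The HSP70 gene HSPA1B (1.75 ± 0.27), FAM117B (1.42 ± 0.26), TMA7 (1.34 ± 0.29), the silencing factor gene TNRC6C (1.33 ± 0.27) and ARNTL (1.3005 ± 0.21) rose, and HSPA1B shares nearly all its sequence with HSPA1A. In RNA CXCL8 (-3.91 ± 0.27), the potassium channel gene KCNA1 (-3.40 ± 0.32), NR4A3 (-2.99 ± 0.31) and CCL20 (-2.95 ± 0.30) fell. MIR33B (3.05 ± 0.30) and MIR33A (1.65 ± 0.14), which lie within the SREBF genes of lipid control, rose with RBPJL (1.63 ± 0.28) and ZNF773 (1.74 ± 0.28), a symbol with an unusually large share of RNA reads. RPF counts were 936 without WT 4 h, 940 without WT 12 h, 862 without ATXN2 KO 4 h, 766 without ATXN2 KO 12 h, 894 without double KO 4 h and 880 without double KO 12 h. RNA counts were 363 without ATXN2 KO 4 h and 383 without ATXN2 KO 12 h.

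The clock genes turned in both assays. PER2 fell 3.12-fold in RNA (-1.64 ± 0.22, edgeR adjusted p = 2.7e-05) and 3.98-fold in RPF (-1.99 ± 0.23, adjusted p = 8.8e-06). NR1D2 fell 2.52-fold in RNA (-1.33 ± 0.14, edgeR adjusted p = 1.19e-06) and by 1.28 ± 0.16 in RPF (adjusted p = 1.69e-05). The clock repressor gene BHLHE40 fell by 0.87 ± 0.12 in RNA and by 0.88 ± 0.13 in RPF. PER1 fell by 0.78 ± 0.11 in RNA. The clock kinase gene CSNK1D fell by 0.53 ± 0.11 in RPF. ARNTL rose 2.46-fold in RPF (edgeR adjusted p = 0.000277), and its RNA rise of 1.08 ± 0.24 (adjusted p = 0.00593) was lost without the ATXN2L KO 4 h or 12 h library (edgeR adjusted p up to 0.164), as was that of BHLHE41 (1.06 ± 0.26, up to 0.241). In RNA, falls of CRY2 (-0.97 ± 0.23) were lost without WT 4 h or WT 12 h, those of PER3 (-0.66 ± 0.16) without any ATXN2 KO or ATXN2L KO library, and the rise of NFIL3 (0.62 ± 0.18) without any of the 8 libraries (edgeR adjusted p up to 0.0536, 0.197 and 0.202). In RPF, falls of TEF (-1.15 ± 0.29) and PER1 (-0.40 ± 0.12) were lost without any ATXN2 KO or double KO library, and PER1 also without any ATXN2L KO library (edgeR adjusted p up to 0.0895 and 0.134). Falls of CRY2 (-0.70 ± 0.19) and PER3 (-0.66 ± 0.16) in RPF were lost without double KO 4 h or 12 h, CRY2 also without ATXN2L KO 4 h and PER3 also without ATXN2 KO 12 h (edgeR adjusted p up to 0.135 and 0.0674). Within lines the 12 h to 4 h ratio of PER2 footprints was 0.257 in WT (exact interval 0.153 to 0.415) and 0.432 in the ATXN2 KO (0.253 to 0.717). It was 0.184 in the ATXN2L KO (0.104 to 0.312) and 0.168 in the double KO (0.0726 to 0.343). For ARNTL footprints it was 2.40 (1.54 to 3.84), 2.10 (1.32 to 3.42), 4.78 (2.61 to 9.59) and 1.88 (1.25 to 2.88) in the same order. The 4.78 rested on 12 counts at 4 h. Each KO interval overlapped that of WT, and these intervals cover counting error only. As a list the core clock was lower in RPF, with 1 up, 8 down and 11 not passing (1 and 8 over the list alone), camera adjusted p = 0.00662, and adjusted p = 0.547 with an estimated correlation. In RNA 3 rose, 6 fell and 13 did not pass (3 and 7 over the list alone), and camera did not pass (adjusted p = 0.0548).

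**Figure D5:**
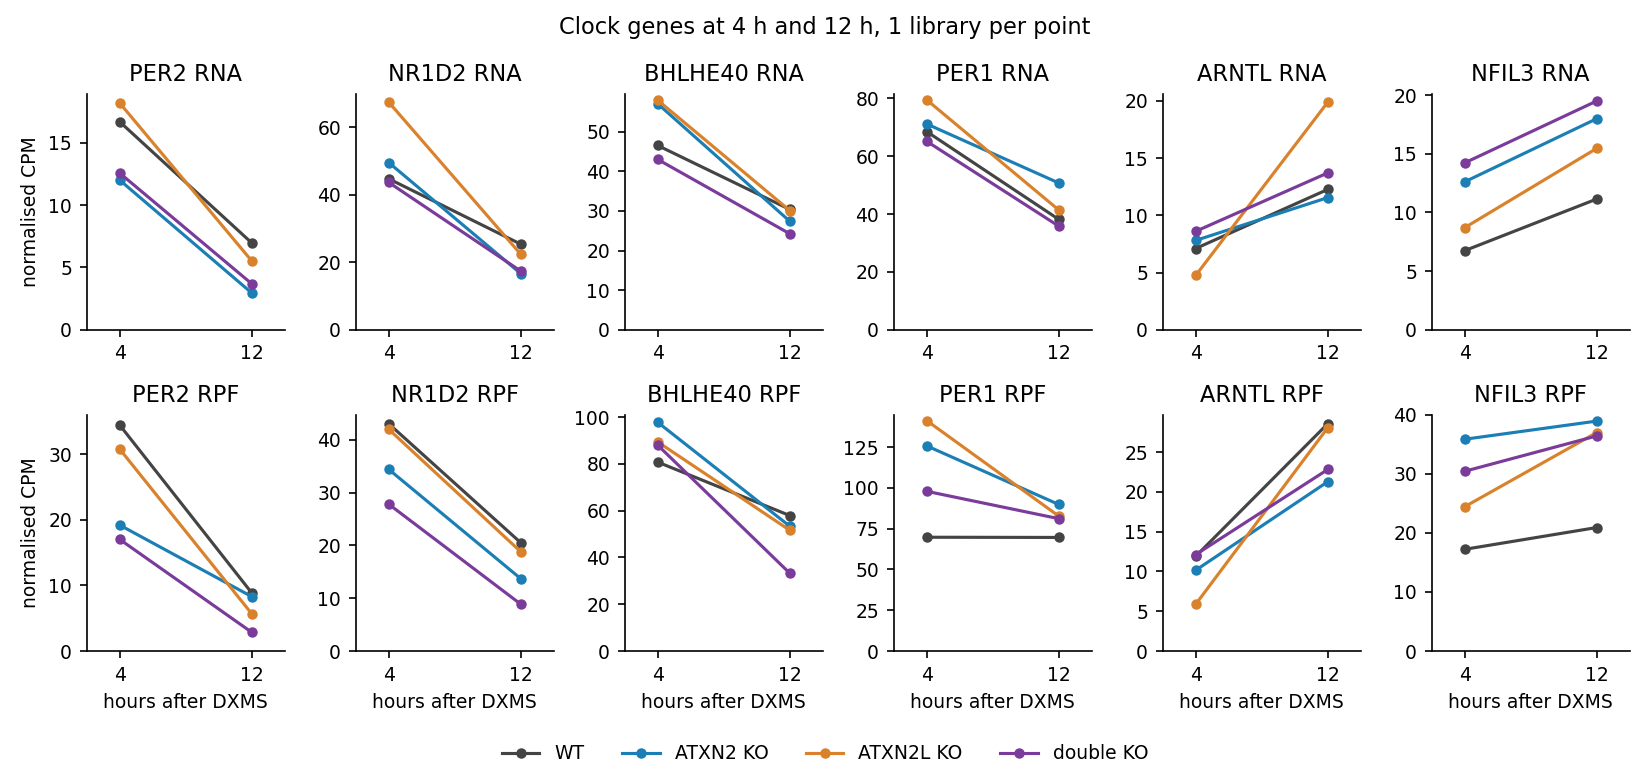
Normalised CPM of PER2, NR1D2, BHLHE40, PER1, ARNTL and NFIL3 at 4 h and 12 h in the 4 lines, RNA above and RPF below. PER2 fell 3.98-fold and ARNTL rose 2.46-fold in RPF across lines.

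Few clock genes differed between KO lines and WT, and each such call was lost when some single library was left out. Footprints of NFIL3, a repressor of clock output, rose by 0.97 ± 0.21 in the ATXN2 KO, 0.70 ± 0.22 in the ATXN2L KO and 0.81 ± 0.21 in the double KO. Those calls were lost without WT 4 h or WT 12 h in each, without ATXN2L KO 12 h in the second and without double KO 4 h or 12 h in the third (edgeR adjusted p up to 0.0525, 0.256 and 0.0978). PER1 footprints rose by 0.61 ± 0.17 in the ATXN2 KO, lost without WT 4 h, ATXN2 KO 4 h or ATXN2 KO 12 h (edgeR adjusted p up to 0.348). They rose by 0.64 ± 0.17 in the ATXN2L KO, lost without WT 4 h or ATXN2L KO 4 h (edgeR adjusted p up to 0.273), and lay below the sum in the double KO (-0.89 ± 0.23), lost without any 4 h library (up to 0.195). In the double KO BHLHE41 footprints fell by 2.11 ± 0.58, lost without WT 12 h or double KO 4 h, and NR1D2 footprints by 0.84 ± 0.22, lost without WT 4 h, WT 12 h or double KO 12 h (edgeR adjusted p up to 0.218 and 0.115). PER2 footprints fell by 1.16 ± 0.32 there, lost without any WT or double KO library (edgeR adjusted p up to 0.201). PER2 lay in a lower stretch of chromosome 2, and with the change of its neighbours removed it no longer passed (-0.73, edgeR adjusted p = 0.144). In RNA of the double KO NFIL3 rose by 0.93 ± 0.28, lost without any WT or double KO library, and BHLHE41 fell by 1.37 ± 0.43, lost without WT 4 h, ATXN2 KO 4 h, double KO 4 h or double KO 12 h (edgeR adjusted p up to 0.205 and 0.223). TIMELESS RNA rose by 0.56 ± 0.16 in the ATXN2L KO, lost without WT 4 h, WT 12 h or ATXN2L KO 4 h (edgeR adjusted p up to 0.141). HLF, a clock output gene, had 4 and 6 RNA counts in WT at the 2 times, 12 and 11 in the ATXN2L KO and 1 in all in the ATXN2 KO (ratio 11.01, exact interval 1.57 to 478). It had 0 in the double KO against 10 in WT, at least 2.56-fold lower at the 3-count floor.

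Inflammatory and early response lists fell with time. All 10 NF-kB genes fell in RPF (10 over the list alone, median -1.93), with camera adjusted p = 4.54e-09, and adjusted p = 0.331 with an estimated correlation. In RNA 8 fell and 1 did not pass (9 over the list alone), with camera adjusted p = 7.47e-11, and adjusted p = 0.205 with an estimated correlation. RELB, an NF-kB subunit gene, fell by 2.0025 ± 0.18 in RPF and by 1.89 in RNA. Immediate early genes fell in RPF (9 down, 4 not passing, and 9 over the list alone), with camera adjusted p = 3.72e-08, and adjusted p = 0.331 with an estimated correlation, and MYC fell by 1.33 ± 0.11. In RNA 10 fell and 4 did not pass (11 over the list alone), with camera adjusted p = 7.47e-11, and adjusted p = 0.205 with an estimated correlation, and CTGF fell by 1.20 ± 0.11. Glucocorticoid-induced genes fell in RNA (6 down, 8 not passing, and 7 over the list alone), with camera adjusted p = 0.00099, and adjusted p = 0.251 with an estimated correlation, and the receptor inhibitor gene ERRFI1 fell by 1.31 ± 0.15. Osteoblast matrix genes fell in RPF (5 down, 16 not passing, and 1 up and 9 down over the list alone), with camera adjusted p = 0.00516, and adjusted p = 0.627 with an estimated correlation. In RNA 5 matrix genes fell and 15 did not pass (1 and 7 over the list alone), with camera adjusted p = 0.00238, and adjusted p = 0.377 with an estimated correlation.

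Protein folding lists split with time. Heat shock genes rose in RPF (9 up, 4 not passing, and 9 over the list alone), with camera adjusted p = 2.54e-06, and adjusted p = 0.373 with an estimated correlation, and the HSP90 cochaperone gene CHORDC1 rose by 0.84 ± 0.11. In RNA 7 rose and 7 did not pass (9 over the list alone), with camera adjusted p = 3.17e-06, and adjusted p = 0.2995 with an estimated correlation, and HSPA1A rose by 1.28 ± 0.15. ER folding genes fell in RPF (5 down, 13 not passing, and 9 over the list alone), with camera adjusted p = 0.00163, and adjusted p = 0.746 with an estimated correlation, and HSPA5, the main ER chaperone gene, fell by 0.81 ± 0.15. In RNA 5 fell and 13 did not pass (7 over the list alone), with camera adjusted p = 0.00099, and adjusted p = 0.554 with an estimated correlation, and EDEM1, which clears misfolded glycoproteins, fell by 0.58.

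Other lists that shifted with time concerned ribosomes, mitochondria and the cell cycle. Ribosomal protein footprints rose slightly (11 up, 1 down, 54 not passing, and 12 and 2 over the list alone), with camera adjusted p = 0.00961, and adjusted p = 0.780 with an estimated correlation. Mitochondrially encoded footprints fell (8 down, 5 not passing, and 10 over the list alone), with camera adjusted p = 0.000754, and adjusted p = 0.649 with an estimated correlation, and MT-CO1 fell by 0.94. The mitochondrial share of footprints went from 0.769 to 0.258% in the ATXN2L KO, whose 4 h library stood apart, from 0.384 to 0.253% in WT, from 0.325 to 0.241% in the ATXN2 KO and from 0.343 to 0.344% in the double KO. Their RNA rose (5 up, 8 not passing, and 8 over the list alone), with camera adjusted p = 8.76e-06, and adjusted p = 0.377 with an estimated correlation, and MT-ATP8 rose by 0.59 ± 0.11. For p53 targets in RPF 6 rose, 1 fell and 13 did not pass (8 and 1 over the list alone), with camera adjusted p = 0.00694, and adjusted p = 0.359 with an estimated correlation. S-phase genes rose in RPF (4 up, 25 not passing, and 4 over the list alone), with camera adjusted p = 0.0102, and adjusted p = 0.780 with an estimated correlation. G2/M genes fell in RPF (3 down, 27 not passing, and 3 over the list alone), with camera adjusted p = 0.0490, and adjusted p = 0.627 with an estimated correlation. In RNA no G2/M gene passed out of 30, while camera gave adjusted p = 0.0157, and adjusted p = 0.251 with an estimated correlation. P-body genes rose in RNA (1 up, 17 not passing, and 1 over the list alone), with camera adjusted p = 0.0110, and adjusted p = 0.251 with an estimated correlation, and the silencing factor gene TNRC6B rose by 0.67 ± 0.11. Stress granule genes rose in RNA by camera (adjusted p = 0.0474, and adjusted p = 0.377 with an estimated correlation) although 0 of 20 genes passed.

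Whether a line changed its response between 4 h and 12 h bears on clock and signalling control. In simulated counts the test of ATXN2 loss recovered 48% of 2-fold and 92% of 4-fold changes in RNA, and 57% and 97% in RPF. The fly protein related to ATXN2 promotes translation of period, so the clock list was of interest, and none of its genes passed. SPTAN1 encodes spectrin, and BDNF a secreted neurotrophin. With ATXN2 loss 46 genes differed in RPF (28 up, 18 down) and 0 in RNA, where DESeq2 found 0 as well. In RNA 715 of the 12705 tested genes had unadjusted edgeR p below 0.05. In RPF DESeq2 found 0 genes with ATXN2 loss and 0 with ATXN2L loss. For loss of either gene 47 RPF genes passed. Nuclear genes among them with known coding length and average log2 CPM of at least 3 were checked against the ATXN2L KO footprint libraries. In 22 of those the level relative to the other lines was higher at 4 h than at 12 h. SPTAN1 and MT-ND4L fell most in that line. CXCL8 passed with ATXN2 loss, yet it fell from 26 to 9 footprint counts in WT, 129 to 1 in the ATXN2 KO, 61 to 2 in the ATXN2L KO and 59 to 1 in the double KO, so a line with ATXN2 intact fell steeply too. BDNF footprints changed from 4 h to 12 h by -0.22 in WT, -1.89 in the ATXN2 KO, -0.39 in the ATXN2L KO and -1.997 in the double KO, the phosphatase gene PTPRR in the same order by -1.05, -1.77, -0.69 and -3.63, and GBA2 by -0.33, 0.80, -0.59 and 0.93. SPTAN1 changed by -0.62, 0.22, -2.46 and 0.11, and MT-ND4L by -0.61, -0.03, -1.55 and 0.87. With ATXN2L loss 4 genes passed in RPF (0 up, 4 down), among them SPTBN1, PLEC and IQGAP1. In RNA 6 did (4 up, 2 down), among them ADA (0.20, 1.14, 1.97 and 3.01 by line), while RLE normalisation left 0, coding genes alone left 1 and DESeq2 gave 7.

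TE compares the change in footprints with the change in RNA, and so asks whether translation moved apart from transcript level. Very few genes passed. DPP9 encodes a dipeptidyl peptidase, TRMT5 a tRNA methyltransferase, KCTD12 a receptor-associated protein and ARPP19 a phosphatase inhibitor. TE changed for 5 genes in the ATXN2 KO, 9 in the ATXN2L KO, 5 in the double KO and 14 with time, where 453, 542, 489 and 639 had unadjusted edgeR p below 0.05. By chance alone a share of 0.05 of the 10674 tested genes would lie below that level. The counts of the KOs lay near or below that share. DPP9 rose by 2.39 ± 0.23, 2.26 ± 0.22 and 2.06 ± 0.23 and TRMT5 by 1.85 ± 0.21, 2.03 ± 0.20 and 1.86 ± 0.22 in the ATXN2 KO, ATXN2L KO and double KO. In each TE comparison limma on the differences between assays called 0 genes. NEFL rose by 1.87 ± 0.22 in the ATXN2 KO and by 1.82 ± 0.22 in the double KO. KCTD12 rose by 2.24 ± 0.44 in the ATXN2L KO (edgeR adjusted p = 0.0238), lost without the WT 4 h, WT 12 h or ATXN2L KO 12 h pair. In the double KO KCTD12 rose by 2.37 ± 0.41 (edgeR adjusted p = 0.00743), lost without the WT 4 h, WT 12 h or double KO 4 h pair. RPRD2 (1.11 ± 0.22) in the ATXN2 KO and POU3F3 (2.59 ± 0.51) in the ATXN2L KO rose too, RPRD2 lost without any WT, ATXN2 KO or double KO pair and POU3F3 without the WT 4 h, WT 12 h or ATXN2L KO 4 h pair. Counts in the ATXN2 KO were 3 without WT 4 h, WT 12 h, ATXN2 KO 4 h or ATXN2 KO 12 h, and in the double KO 3 without WT 4 h, WT 12 h or double KO 4 h. In the ATXN2L KO they were 4 without WT 4 h, 3 without WT 12 h and 27 without ATXN2L KO 12 h.

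TE of mitochondrially encoded mRNAs was higher in the ATXN2L KO (1 up, 12 not passing, and 12 over the list alone, median 1.22), with camera adjusted p = 6.59e-10, and adjusted p = 0.778 with an estimated correlation. MT-ND3 rose by 1.59 ± 0.29, a call lost without the WT 4 h or WT 12 h pair (edgeR adjusted p up to 0.998), and the 4 h ATXN2L KO footprint library had an unusually large mitochondrial share. Without the 4 h ATXN2L KO libraries 1 library of that line was left per assay, so only the direction of a list is given here. The mitochondrial list still pointed up in TE, but its footprint list pointed down. At 12 h the median log2 footprint difference from WT was 0.012 over these genes, with 9 of 13 higher, so their footprints moved little. What was left of the TE rise thus went with lower mitochondrial RNA and not with more footprints. TE of ribosomal protein genes rose in the ATXN2L KO by camera (adjusted p = 0.000441, and adjusted p = 0.778 with an estimated correlation) although 0 of 66 genes passed. Without the 4 h libraries that list also pointed up in TE and down in footprints, and ribosomal protein RNA was lower in this line. With time ARPP19 (1.01 ± 0.17), HMGB1 (0.98 ± 0.19), HIST2H2BE (0.93 ± 0.17) and HIST1H4I (0.87 ± 0.17) rose in TE, and SRSF5 (-1.17 ± 0.19), MT-ND1 (-1.35 ± 0.26), MT-ND2 (-1.24 ± 0.25) and MT-CO1 (-1.11 ± 0.23) fell. All TE time calls were lost, with 0 left, without the WT 4 h, WT 12 h, ATXN2 KO 4 h or ATXN2 KO 12 h pair. The mitochondrial list fell in TE with time (5 down, 8 not passing, and 13 over the list alone), with camera adjusted p = 4.25e-13, and adjusted p = 0.774 with an estimated correlation. Other TOP mRNAs fell in TE (1 down, 20 not passing, and 2 over the list alone), with camera adjusted p = 0.0418, and adjusted p = 0.774 with an estimated correlation, and PABPC1, the gene of poly(A)-binding protein, fell by 0.79 ± 0.14.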

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

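The tests of the ATXN2L KO at both times and of coding length were chosen only after the results were seen.

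In the 4 h ATXN2L KO footprint library, mitochondrially encoded mRNA took 0.769% of counts against 0.325 to 0.384% in the other 4 h footprint libraries, which marked it as far from the others. Its reads in genes made up 15.0% against 27.4 to 32.1% in those libraries, and its reads outside genes 14.02% against 8.49 to 9.98%. Its reads placed at several sites made up 70.7% against 58.8 to 62.1%. What these shares did to the footprint changes of the ATXN2L KO was not tested. For 22 nuclear genes that had passed the tests of time change by loss, the same library also stood high. Their level relative to the other lines was higher in it than in the 12 h ATXN2L KO footprint library. Among them were the long cytoskeletal genes SPTAN1 and PLEC. Only genes with known coding length and average log2 CPM of at least 3 were counted. A lasting change of the ATXN2L KO line is unlikely for the mitochondrial footprints, because their median log2 difference from WT was 1.09 at 4 h and 0.012 at 12 h (chosen afterwards). RNA fragments not protected by ribosomes could be a part of it, since nuclear genes with a similar RNA to footprint ratio deviated by 0.630, but only 5 such genes existed and the question stays open. A trend with coding length could be a part of the higher long genes and stays open, since the library rose with length (rank correlation 0.298, class medians -0.24 to 0.36) but taking the trend out moved their median deviation only from 1.08 to 0.954, a test on genes picked for standing high.

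Other libraries stood apart from the 3 others of their time and assay. The 4 h ATXN2L KO RNA library had 4.71 M gene counts against 2.89 to 3.10 M. The 12 h double KO RNA library had 50.6% of its counts in its 10 largest genes against 39.9 to 41.2%. The 12 h ATXN2 KO footprint library had 5.56% of reads outside genes against 6.67 to 6.89%. The 12 h double KO footprint library had a mitochondrial mRNA share of 0.344% against 0.241 to 0.258%. The change from 4 h to 12 h stood apart for ARNTL RNA in the ATXN2L KO (ratio 4.19 against 1.48 to 1.73) and for CRY1 RNA in the double KO (0.738 against 1.05 to 1.12). Chance marks about 1 in 20 such groups, and 5 of 32 library measures and 2 of 28 clock gene ratios were marked.

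The test of whether a time change differed between lines marked 46 genes in RPF with ATXN2 loss, 4 in RPF with ATXN2L loss and 6 in RNA with ATXN2L loss. With ATXN2 loss the difference was 1.89 for SPTAN1, 1.61 for MT-ND4L, 1.43 for GBA2, -4.06 for CXCL8 (a fitted value resting on 1 or 2 counts in each KO line at 12 h), -2.49 for PTPRR and -1.66 for BDNF. With ATXN2L loss it was -1.06 for SPTBN1, -1.04 for PLEC and -0.99 for IQGAP1 in RPF. In RNA with ATXN2L loss it was 1.83 for ADA, 1.505 for MIR4454, 1.499 for NR2F2-AS1 and -1.68 for MT-TV. The 4 lines allow only 3 pairings, too few to judge chance. For ATXN2 loss in RPF the real pairing gave 46 and the highest other 4, so 1 of 3 pairings gave as many. For ATXN2L loss in RPF the real pairing gave 4 and the highest other 46, so 3 of 3 gave as many. In RNA the real pairing gave 0 for ATXN2 loss with 6 as the highest other (3 of 3), and 6 for ATXN2L loss with 0 as the highest other (1 of 3).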

How the results depend on the processing

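Fits with neighbours removed, on coding genes only and without mitochondrial genes were chosen only after the results were seen. For 859 results of named genes, counted once per alternative, 9737 combinations kept direction and side of the threshold, 577 became weaker, 61 became stronger and 1 reversed, which was DNAJB1 RNA in the ATXN2L KO with neighbours removed (-0.014). Depth limited genes below about 10 counts, and fits that left out a library assumed that the lone library varied like the others. Such fits were not run for the tests of time change by loss, which then have no residual degrees of freedom. Comparisons are given in the order ATXN2 KO, ATXN2L KO, double KO, and except where stated the cause was not tested.

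With DESeq2, RNA gave 578, 844 and 614, time 322, departure 236, and 3 and 300 for the double KO against the ATXN2 KO and ATXN2L KO. DESeq2 in RPF gave 1113, 1329 and 1276, time 635, departure 459, 749 against the ATXN2L KO, and 0 and 0 for time change by ATXN2 and ATXN2L loss, and DESeq2 gave 3 in TE for the ATXN2 KO. With no time term the spread over time enters the error, and RNA gave 534, 970 and 547, RPF 598, 842 and 814, and TE 2, 2 and 0. With neighbours removed, RNA gave 1619 for the ATXN2L KO and 462 for the double KO against it, and RPF gave 1415, 1469 and 1557, departure 625 and 889 against the ATXN2L KO. The overlap of all 3 KOs in RPF was then 554. With no filter, the double KO against the ATXN2 KO gave 43 in RNA and 112 in RPF, time change by loss gave 12 and 35 in RNA, and TE gave 11, 26 and 19 with 42 for time. RNA time change by ATXN2L loss gave 0 with RLE and 1 with coding genes only. TE gave 0, 0, 0 and 0 with limma, and 9 for time without mitochondrial genes. Over all list results, 57 passed camera with the preset correlation, 0 passed with an estimated correlation and 34 passed fry. These are separate totals, and the 34 need not be among the 57.

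With 1 library left out, RNA ranged from 478 to 1916, 1219 to 2570 and 787 to 1907, time 363 to 830, departure 227 to 959, and 1 to 50 and 329 to 1044 for the double KO against the ATXN2 KO and ATXN2L KO. RPF ranged from 613 to 2739, 976 to 2517 and 822 to 2886, time 766 to 1329, departure 267 to 1627, and 3 to 121 and 545 to 1567 for the double KO against the single KOs. TE ranged from 3 to 6, 3 to 27 and 3 to 7, and time 0 to 19.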

Other observations

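The test of mitochondrial RNA as a whole, the tests outside shifted windows and of additivity, and the test of how the double KO line arose were chosen only after the results were seen.

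Several mitochondrial tRNAs, which decode mRNAs made inside mitochondria, had fewer reads in the KO lines than in WT, with 9, 10 and 7 of 15 passing as lower in the ATXN2 KO, ATXN2L KO and double KO. MT-TM, the methionine tRNA needed for initiation there, was lower by -3.18 in the ATXN2 KO, -3.67 in the ATXN2L KO and -3.31 in the double KO. MT-TH changed by -2.89, -3.17 and -2.84 and MT-TP by -1.92, -2.23 and -1.88 in the same order. MT-TI changed by -1.33, -1.38 and -1.34, and MT-TL1 by -1.22, -1.22 and -0.98. MT-TR rose by 0.79 in the ATXN2 KO and 0.75 in the ATXN2L KO, and MT-TF by 0.67 in the double KO. Mitochondrial tRNA took 20.2 and 21.5% of RNA counts in WT and 9.85 to 12.5% in the KO lines. Every KO was compared with the same WT libraries, which also differed in make-up. Reads placed at several sites made up 50.7 and 49.5% in WT against 40.8 to 43.5% in the KO lines. Reads in genes made up 27.0 and 28.2% against 31.3 to 34.7%. A difference of the WT libraries thus cannot be told from an effect of the KOs.

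An equal loss of all short RNA in library preparation is an unlikely explanation for the whole of the lower mitochondrial tRNA reads. Nuclear noncoding genes under 200 bases had median changes of -0.044 in the ATXN2 KO, -0.143 in the ATXN2L KO and 0.098 in the double KO, against -0.823, -0.983 and -0.619 for mitochondrial tRNA. More of these short nuclear genes passed as lower than as higher (49 and 17, 87 and 26, 44 and 39), so a part may come from preparation. Less mitochondrial RNA as a whole may account for a part, with medians for mitochondrial mRNA and rRNA of -0.278 in the ATXN2 KO, -0.481 in the ATXN2L KO and only -0.063 in the double KO (chosen afterwards), and the question stays open.

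The sharing of changes among all 3 KO lines (957 RPF genes) went beyond the spread of the shared WT libraries between times, since simulations with unchanged lines gave at most 0 such genes, but a lasting feature of the single WT line could not appear there and stays open. Copy-number segments could explain a part, because the 10 flanking genes moved by 0.248 of the gene's own change, and by 0.167 outside shifted windows (chosen afterwards), and neither value settles it. Of the 741 genes changed in RNA in all 3 lines 591 were tested in footprints and 98.8% of these moved the same way, which leaves a part by short noncoding RNA, absent from the footprint files, open. Separate effects that add up are unlikely as the sole explanation, as the double KO change was 0.507 of the sum of the single changes (chosen afterwards). A lasting feature of the single WT line would lower that ratio too, so it does not test how both proteins combine. A double KO line derived from the ATXN2 KO line is a candidate explanation for their common segments, because 0 windows were shifted between them while 10 windows were shifted with one sign in both against WT (chosen afterwards).

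The window with the largest change with time lay on chromosome 6 from 26.2 to 30.6 Mb, where histone genes cluster, and it was the only 1 shifted. For the time counts, 8 groupings of the libraries part the 4 line pairs as the real one does, too few to judge chance. The real grouping gave 863 genes in RNA, 1436 in RPF and 14 in TE, with 0 as the highest other in each, so 1 of 8 gave as many. The other groupings that could be fitted, of 32 in all, part fewer pairs and gave at most 32 in RNA, 1 in RPF and 0 in TE. For the departure from the sum only 3 pairings exist, too few to judge chance. The real pairing gave 868 genes in RNA with 1619 as the highest other, and 1101 in RPF with 2537, so 3 of 3 gave as many.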
